A study of Mus musculus with 8 samples.

How the data were processed

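RNA was measured in VE-cadherin-positive cells sorted from the aorta-gonad-mesonephros region of mouse embryos at stage E11.5. The cells were kept in serum-free medium with VEGF at 20 ng/ml and other haematopoietic cytokines at 50 ng/ml, and were treated for 8 hours with DMSO, 25 uM forskolin, 4 ng/ml BMP4 or both. Each of the 4 groups had 2 biological replicates, so 8 arrays in all. RNA was amplified with a NuGen kit, labelled with biotin and hybridised to Affymetrix mouse arrays. The deposited values are log2 expression per probe set and were already normalized by the authors. Their notes name R 2.15 as the tool. The background correction, the normalization, the summarisation of probes and any filter that left these probe sets are not stated. The log2 scale was read from the range of the values, 2.10 to 14.66, and the array medians lay between 6.92 and 7.01. No background or detection values accompany the table, so the signal over background of each gene is unknown, and for arrays the number of replicates sets the precision.

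The table holds 20757 probe sets. Of these, 17686 carry 1 gene symbol, 249 carry several and 2822 carry none, and the last 2 kinds (3071 in all) were left out of the tests of genes. Where a gene had more than 1 probe set, as 96 genes did, the probe set with the highest mean over all 8 arrays was used, which gave 17587 genes. Gene identifiers were found in the reference gene table for 17542 probe sets or genes, and 0 symbols needed an update. No filter on dim genes was applied.

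A linear model with 1 mean per group was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation without trend (4 residual and 2.6 prior degrees of freedom). The contrasts were forskolin, BMP4 and both treatments each against DMSO, both treatments against forskolin and against BMP4, the difference of the forskolin effect with and without BMP4, forskolin averaged over BMP4, and BMP4 averaged over forskolin. The comparisons with DMSO share the DMSO arrays. Benjamini-Hochberg adjustment was made over all genes in each contrast, with a threshold of 0.05, and intervals are at 95%. The groups, contrasts, tests of genes and of the 29 lists, named-gene rule and alternatives were fixed before the data were examined. The added lists, the test of all probe sets, the simulation of the difference of effects and the tests of hepatic, gastric, peptide and interferon patterns were not among these.

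The replicate numbers are shared between groups by number alone, and the labels state no link between arrays with the same number, so the model held no replicate term. The result with it is given with the alternatives.

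A set of 29 gene lists was tested in the 8 contrasts, 232 tests in all, with camera of limma, two-sided, with its preset inter-gene correlation of 0.01 and adjustment over the lists in each contrast. The lists held cAMP/CREB-responsive genes, cAMP/PKA components, BMP/SMAD targets, BMP components, TGF-beta/SMAD3 targets, haematopoietic transcription factors, stem and progenitor surface genes, endothelial, arterial and Notch, venous, shear-stress, prostaglandin, S-phase, G2/M, erythroid, macrophage, mesenchymal, mesonephric, neural crest, NF-kappaB, JAK/STAT, interferon, p53, unfolded protein, hypoxia, heat-shock, cholesterol, MAPK feedback and angiogenic genes. Camera was repeated with the correlation estimated from the residuals, and fry was run beside it. Members of a list were judged over all genes and adjusted over the list alone. A list needed 5 measured members. Lists of hepatic, gastric and peptide genes were added after some of their members had been seen, and tests on them used members not seen before.

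The genes named were, by rule, the 6 largest rises and the 6 largest falls among genes that passed in each pairwise contrast with the arrays of the groups apart, up to 4 passing members of each list with the smallest p, and a panel of 19 genes whether or not they passed. Where no gene passed, the 5 with the smallest p were named. Further list members are named as examples.

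The alternatives tried were repeated quantile normalization, subtraction of array medians, array weights, the mean of a gene's probe sets, removal of the lowest 30% of genes by mean, a trended and robust spread, a replicate block, a fit of only the arrays compared, a minimum log2 difference of 1, omission of each array in turn, and a test of all probe sets, the last chosen after the data had been seen. Counts of genes in other splits of the arrays came from a fit of 2 groups. Likeness of effects was the Pearson correlation across genes of effects that share no arrays.

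The tests were checked on simulated data with 17587 genes in 10 runs. With forskolin averaged over BMP4, 12.2% of genes changed by 0.5 on the log2 scale were recovered, 81.3% of those changed by 1 and 98.2% of those changed by 2, with 3.77% of the calls false. For a comparison of 2 groups of 2 arrays, as in forskolin against DMSO, 0.746%, 45.8% and 93.8% were recovered, with 4.71% of the calls false. The other pairwise comparisons have the same number of arrays, and BMP4 averaged over forskolin has the design of the forskolin average. For the difference of effects, simulated with 200 changed genes per run, 0.6% of differences of 0.5 were recovered, 7.8% of those of 1, 78% of those of 2 and 96.4% of those of 3, with 6.26% of the calls false. This last check was added after the data had been seen. Camera called lists of 20 genes shifted by 0.3 in 10 of 10 runs and unshifted lists in 0 of 10, by an unadjusted p under 0.05. The simulated genes varied independently. This check therefore does not cover lists of correlated genes, such as the TGF-beta/SMAD3 list with an estimated correlation of 0.28.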

Results

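Gene expression was measured on 8 arrays in VE-cadherin-positive cells, a sorted fraction rich in endothelial cells, from the mouse aorta-gonad-mesonephros region at stage E11.5. This region is where blood stem cells form from the lining of the dorsal aorta. The cells were cultured for 8 hours with the solvent DMSO, with 25 uM forskolin, with 4 ng/ml BMP4, or with forskolin and BMP4 together. Forskolin activates adenylyl cyclase and so raises cAMP, while BMP4 is a ligand of the BMP receptors that act through SMAD1 and SMAD5. Each of the 4 groups had 2 biological replicates, and this number of arrays limits the precision of every value. Expression could be compared for 17587 genes. Values below are log2 differences between group means ± the standard error from limma, with n = 2 arrays per group unless stated. The median standard deviation between replicates of a gene was 0.135 in the DMSO group, 0.141 with forskolin, 0.117 with BMP4 and 0.151 with both treatments. In every pairwise comparison, all genes that passed the test had both arrays of one group above both arrays of the other. The test picks genes whose groups differ by more than their spread, so such separation, here and in the averages below, is no separate evidence.

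Forskolin was compared with DMSO to ask what raised cAMP did on its own. The largest rises were in Slc35f3, a transporter-like gene, by 3.57 ± 0.26 (adjusted p = 0.0168), and in Inhbb, the inhibin beta B subunit of activin B, by 3.36 ± 0.16 (adjusted p = 0.00286). Inhbb had a mean of 11.11 ± 0.05 (SD, n = 2) with forskolin and 7.74 ± 0.14 (SD, n = 2) with DMSO. The lymphatic and sinusoidal endothelial marker Lyve1 rose 3.32-fold, and the water channel Aqp1 rose 4.01-fold. Tnfrsf11b, which encodes the decoy receptor osteoprotegerin, fell by 2.93 ± 0.14 (adjusted p = 0.00286). The prostaglandin-degrading enzyme gene Hpgd fell by 1.89 ± 0.16 (adjusted p = 0.025). In all, 13 genes rose and 6 fell. Fam110c (2.53), Ct55 (2.51) and the lipopolysaccharide co-receptor gene Cd14 (2.11) were among the other rises. The remaining falls were Nav3 (-1.37), the platelet and lymphatic receptor gene Clec1b (-1.25), Depp1 (-1.07) and the iron exporter gene Slc40a1 (-1.07).

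Of the 39 measured cAMP/CREB-responsive genes, 0 passed over all genes in forskolin against DMSO. With p adjusted over the list alone, 10 were higher and 1 was lower. Among them were the phosphodiesterase gene Pde10a at 2.20, the phosphatase gene Dusp5 at 1.04 and the coactivator gene Ppargc1a at 1.84, and the lower one was Arc at -0.97. The list as a whole shifted up by a median of 0.32, with 31 of 39 members higher (camera adjusted p = 9.1e-09), and it had adjusted p = 0.068 with an estimated correlation. The early cAMP targets Nr4a1 (0.30), Fos (0.36) and Crem (0.49) did not pass, nor did Per1 (0.30), Pde4b (1.18) and Pde4d (1.11). The 24 measured BMP/SMAD target genes had a median of 0.12 and the list did not pass (adjusted p = 0.15), with Id1 at 0.10, Id2 at 0.49, Id3 at 0.19, Smad6 at 0.14, Smad7 at 0.18 and Bambi at -0.52. Transcripts of the ligand gene Bmp4 differed by 0.32 (adjusted p = 0.644). Runx1, the transcription factor needed for the endothelial-to-blood transition, differed by -0.03 (adjusted p = 0.984). Gata2 (0.27), Klf2 (0.56), Cdh5 (0.26), Ptprc (0.09) and Kit (0.77) also did not pass. Among panel genes that passed with a trended and robust spread in limma were Kit (adjusted p = 0.0035), Bambi (0.0053), Pde4d (0.0086) and Pde4b (0.022).

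Other lists shifted with forskolin alone under the preset correlation and lost the call when the correlation was estimated. Of 18 angiogenic and permeability genes, 0 passed over all genes, while 9 were higher and 2 lower when adjusted over the list alone, among them Angpt2 (1.15) and the sphingosine receptor gene S1pr1 (0.64). Their median was 0.33, with adjusted p = 0.011 and adjusted p = 0.48 with an estimated correlation. Of 17 TGF-beta/SMAD3 target genes, 0 passed over all genes and 3 were higher when adjusted over the list alone, namely Skil, Tgfbi and Pmepa1. The TGF-beta list had a median of 0.25, with adjusted p = 0.015 and adjusted p = 0.48 with an estimated correlation. Of 23 endothelial markers 1 rose, Lyve1, with a list median of 0.11, adjusted p = 0.015 and adjusted p = 0.48 with an estimated correlation. Of 19 S-phase genes, 16 were lower and 0 passed over all genes, while Ccne1 (-0.60) was lower when adjusted over the list alone, with a list median of -0.13, adjusted p = 0.026 and adjusted p = 0.48 with an estimated correlation. Of 15 interferon-response genes, 13 were lower and 0 passed over all genes, while 8 were lower when adjusted over the list alone. The interferon list had a median of -0.66, with adjusted p = 3.6e-07 and adjusted p = 0.22 with an estimated correlation. Its means were highest in the DMSO arrays, 7.95 and 8.22 against at most 7.40 in the others, which bears on every comparison with DMSO. For forskolin with BMP4 present its median was -0.09. Transcripts of hepatic cells also had lower values, with a median of -0.64 over 20 such genes and no gene past the test (camera p = 4e-05, and 0.2 with an estimated correlation).

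The forskolin test rested on few arrays. The count of 19 genes came to between 0 and 7 when any 1 of the 8 arrays was left out and to 262 when the spread was modelled with a trend and robustly. Of the 13 named genes that passed, 0 passed in all 8 omissions by limma, and Aqp1, Nav3, Clec1b, Depp1 and Slc40a1 passed in none. Leaving out Forskolin replicate 1 ended the TGF-beta call (adjusted p = 0.34), leaving out DMSO replicate 2 (0.19) or Forskolin replicate 2 (0.32) ended the S-phase call, and leaving out Forskolin replicate 2 ended the angiogenic call (0.052), while the endothelial call ended without DMSO replicate 1 (0.064), Forskolin replicate 1 (0.07) or Forskolin replicate 2 (0.066).

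**Figure D1:**
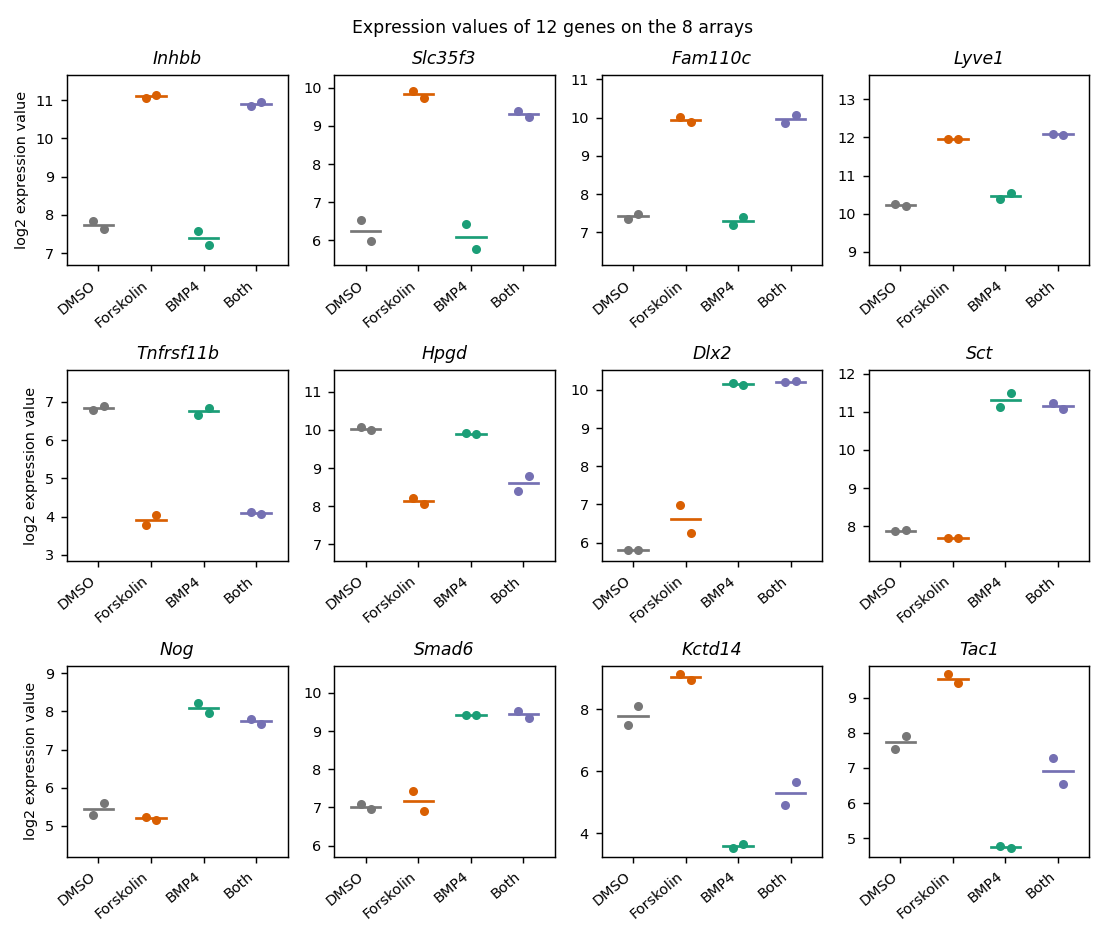
Log2 expression (vertical axis) of 12 named genes in each array (points) and the mean of each group of 2 arrays (lines). Inhbb stood at 11.11 with forskolin and 7.74 with DMSO, and Dlx2 at 10.16 with BMP4 and 5.81 with DMSO.

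BMP4 was compared with DMSO to measure the response to the ligand by itself. The homeobox gene Dlx2 rose most, by 4.35 ± 0.23, which is 20.4-fold (adjusted p = 0.00416), from 5.81 to 10.16. The WNT antagonist genes Wif1 and Dkk1 rose by 3.54 ± 0.23 and 3.46 ± 0.32 (adjusted p = 0.00641 and 0.024). Sct, which encodes the hormone secretin, rose by 3.42 ± 0.16, and the cardiac transcription factor gene Tbx20 by 2.81 ± 0.16. The secreted BMP antagonist gene Nog rose 6.31-fold and the inhibitory SMAD gene Smad6 rose 5.25-fold. The largest falls were Kctd14, by 4.20 ± 0.30 (adjusted p = 0.00797), and the substance P precursor gene Tac1, by 2.97 ± 0.26 (adjusted p = 0.0213). The lectin gene Chodl fell by 1.48 ± 0.16 (adjusted p = 0.0463). In all, 14 genes rose and 3 fell.

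Of the 24 BMP/SMAD target genes, 5 rose with BMP4, 0 fell and 19 did not pass over all genes, while 19 were higher when adjusted over the list alone. The 5 were Dlx2, Nog, Smad6, Msx2 and Id2, the last by 1.79 ± 0.14 (adjusted p = 0.0126). The list median was 1.19, with 22 of 24 members higher (adjusted p = 1e-35), and the call held with an estimated correlation (adjusted p = 0.0042). The classical targets Id1 (1.11, adjusted p = 0.136), Id3 (0.72, adjusted p = 0.158) and Smad7 (1.55, adjusted p = 0.0865) did not pass over all genes. With a trended and robust spread in limma they did (adjusted p = 0.0025, 0.00026 and 0.0076). The cAMP/CREB-responsive list had a median of -0.06 and did not pass (adjusted p = 0.8). Among panel genes of blood formation, Runx1 differed by 0.20 (adjusted p = 0.993), Gata2 by 0.50 (adjusted p = 0.573), Kit by -0.05 and Ptprc by -0.59, and none passed. Klf2 (-0.29) and Bambi (0.10) did not pass either. All 15 interferon-response genes had lower values with BMP4, 0 of them past the test over all genes and 6 when adjusted over the list alone, with a median of -0.66, adjusted p = 5.3e-11 and adjusted p = 0.1 with an estimated correlation. The 17 TGF-beta/SMAD3 target genes had a median of 0.23, with 0 past the test over all genes and 1 higher when adjusted over the list alone (adjusted p = 0.0011, and adjusted p = 0.8 with an estimated correlation). The count of 17 genes came to 0 without either DMSO array, 1 without either BMP4 array, 13 without either array of the combined treatment and 14 without either forskolin array. Of the 11 named genes that passed, 0 passed in all 8 omissions by limma, and Chodl passed in none. The count came to 9 with only the arrays compared in the fit, and to 31 with a trended and robust spread.

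The combined treatment was compared with DMSO to see the joint response. Genes of both single treatments were among the largest changes. Dlx2 rose by 4.41 ± 0.23 (21.3-fold, adjusted p = 0.00215) and Wif1 by 3.75 ± 0.23, as they did with BMP4, while Inhbb rose by 3.16 ± 0.16 (8.94-fold, adjusted p = 0.00215), as it did with forskolin. The activin antagonist gene Fst rose by 3.10 ± 0.29 and the neuropeptide Y gene Npy by 3.09 ± 0.41 (adjusted p = 0.0139 and 0.0444). Tnfrsf11b fell by 2.74 ± 0.14, the bone matrix gene Dmp1 fell by 2.64 ± 0.28 and Kctd14 fell by 2.50 ± 0.30. The sodium channel subunit gene Scn4b fell by 2.22 ± 0.25, the growth factor gene Fgf5 fell by 1.91 ± 0.16 and the nucleotide receptor gene P2ry6 fell by 1.74 ± 0.19. In all, 59 genes rose and 26 fell.

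Of the 39 cAMP/CREB-responsive genes 4 rose with both treatments, 0 fell and 35 did not pass, while 17 were higher and 3 lower when adjusted over the list alone. The 4 were the peptide hormone gene Vip (1.64), Pde10a (1.94), Dusp5 (0.94) and Pde4d (1.18). Vip had a mean of 6.5 with both treatments, against 4.65 with forskolin, 4.86 with BMP4 and 4.86 with DMSO, so it was not higher with forskolin alone. The cAMP/CREB-responsive list had a median of 0.37, with adjusted p = 1.5e-10, and the call held with an estimated correlation (adjusted p = 0.026). Of the 24 BMP/SMAD target genes 11 rose, 0 fell and 13 did not pass, while 20 were higher when adjusted over the list alone, with a median of 1.63, adjusted p = 6.4e-30 and adjusted p = 0.006 with an estimated correlation. Here Id1 (1.14, adjusted p = 0.0466) and Smad7 (1.63, adjusted p = 0.034) passed, beside Nog (2.30), Smad6 (2.41) and Id2 (1.76), while Id3 (0.79, adjusted p = 0.0518) did not. Lyve1 rose by 1.85 ± 0.12, Aqp1 by 2.33 ± 0.21 and Cd14 by 2.16 ± 0.23, and Hpgd fell by 1.43 ± 0.16. The interferon-induced gene Ifit2 fell by 1.59 ± 0.19, the 1 interferon-response gene to pass over all genes. All 15 members of that list were lower, 7 of them when adjusted over the list alone, with a median of -0.67, adjusted p = 1.5e-10 and adjusted p = 0.075 with an estimated correlation. The 17 TGF-beta/SMAD3 target genes had a median of 0.36, with 4 higher when adjusted over the list alone (adjusted p = 0.0011, and adjusted p = 0.68 with an estimated correlation). Runx1 (0.22), Gata2 (0.69), Kit (0.63), Klf2 (0.53), Crem (0.60), Pde4b (1.04), Bambi (-0.07) and Bmp4 (-0.20) did not pass. With a trended and robust spread in limma Id3 (adjusted p = 6.4e-05), Kit (0.0084), Gata2 (0.017) and Pde4b (0.03) passed. Leaving out any 1 of the 8 arrays brought the count of 85 to between 8 and 35, and of the 26 named genes that passed, 4 (Dlx2, Sct, Inhbb and Tnfrsf11b) passed in all 8 omissions. In none of them did 9 of the 26 pass, namely Npy, Kctd14, P2ry6, Pde10a, Dusp5, Pde4d, Hpgd, Ifit2 and Id1.

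The combined treatment was set against forskolin alone to isolate BMP4 in the presence of raised cAMP. Dlx2 rose by 3.60 ± 0.23 (12.1-fold, adjusted p = 0.0109), Sct by 3.46 ± 0.16 (adjusted p = 0.00366), Wif1 by 3.07 ± 0.23 and Nog by 2.54 ± 0.16. Smad6 rose by 2.27 ± 0.19, the homeobox gene Msx2 by 2.28 ± 0.23 and the helix-loop-helix inhibitor gene Id4 by 1.61 ± 0.14. Kctd14 fell by 3.75 ± 0.30, Tac1 by 2.64 ± 0.26, Fgf5 by 2.01 ± 0.16 and the neuronal adhesion gene Opcml by 1.22 ± 0.12. Opcml was dim, with a mean of 3.49 with both treatments and 4.71 with forskolin. In all, 13 genes rose and 4 fell. Of the 24 BMP/SMAD target genes 5 rose over all genes and 21 were higher when adjusted over the list alone, with 23 of 24 higher in value and a median of 1.24. That list passed with the preset correlation (adjusted p = 1.4e-39) and with an estimated correlation (adjusted p = 0.0034). Id2 (1.27, adjusted p = 0.0528), Id1 (1.04, adjusted p = 0.176) and Smad7 (1.45, adjusted p = 0.146) did not pass over all genes. The cAMP/CREB-responsive list had a median of -0.02 (adjusted p = 0.82) and the interferon list one of -0.07, and neither passed.

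Small downward shifts appeared in 3 further lists when BMP4 was added to forskolin, each lost with an estimated correlation. The 19 mesenchymal markers had a median of -0.27, with 0 past the test over all genes and 2 lower when adjusted over the list alone (adjusted p = 0.045, and adjusted p = 0.77 with an estimated correlation). The 17 mesonephric, gonadal and epithelial markers had a median of -0.19, with 13 lower (adjusted p = 0.027, and adjusted p = 0.74 with an estimated correlation). The angiogenic and permeability genes had a median of -0.12, with 1 of 18 lower when adjusted over the list alone (adjusted p = 0.045, and adjusted p = 0.77 with an estimated correlation). Leaving out Forskolin+BMP4 replicate 1 (adjusted p = 0.062), Forskolin replicate 2 (0.18) or Forskolin+BMP4 replicate 2 (0.19) ended the mesonephric call, leaving out either DMSO array (0.072), Forskolin replicate 1 (0.47), Forskolin+BMP4 replicate 1 (0.28) or replicate 2 (0.19) ended the mesenchymal call, and any array but Forskolin+BMP4 replicate 1 ended the angiogenic call (0.055 to 0.57). The count of 17 genes fell to 0 without either array of the combined treatment, and was 1 to 3 without any other array. Of the 11 named genes that passed, 0 passed in all 8 omissions and 7 passed in none, namely Wif1, Msx2, Id4, Kctd14, Tac1, Fgf5 and Opcml.

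Forskolin in the presence of BMP4 was measured by setting the combined treatment against BMP4 alone. Inhbb rose by 3.51 ± 0.16 (11.4-fold, adjusted p = 0.00339), Slc35f3 by 3.21 ± 0.26, Fam110c by 2.69 ± 0.14 and Aqp1 by 2.30 ± 0.21. Ct55 rose by 2.24 ± 0.21, the potassium channel gene Kcnj8 by 1.94 ± 0.16 and Lyve1 by 1.61 ± 0.12 (adjusted p = 0.0417, 0.0274 and 0.0191). Tnfrsf11b fell by 2.66 ± 0.14 (adjusted p = 0.00339), Dok4 by 1.40 ± 0.14, the growth factor gene Pdgfa by 1.21 ± 0.13, Exoc3l2 by 1.13 ± 0.11 and Depp1 by 1.10 ± 0.11. In all, 14 genes rose and 5 fell. Of the 39 cAMP/CREB-responsive genes 0 passed over all genes, while 16 were higher and 1 lower when adjusted over the list alone, with a median of 0.39 and adjusted p = 2e-11, and the call held with an estimated correlation (adjusted p = 0.041). The 24 BMP/SMAD target genes had a median of 0.06 and did not pass (adjusted p = 0.18), with Id1 at 0.03, Id2 at -0.04, Smad6 at 0.02 and Smad7 at 0.08. Klf2 (0.82, adjusted p = 0.0711), Kit (0.69, adjusted p = 0.104), Crem (0.90), Pde4d (1.12) and Pde4b (1.16) did not pass. The interferon list had a median of -0.09 and did not pass.

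In the same comparison both cell-cycle lists shifted down under the preset correlation, with 0 members past the test over all genes. Of the 19 S-phase genes 16 were lower, with a median of -0.19, adjusted p = 0.012 and adjusted p = 0.57 with an estimated correlation. The 19 G2/M genes had a median of -0.10, with adjusted p = 0.048 and adjusted p = 0.46 with an estimated correlation. Leaving out BMP4 replicate 1 (0.11) or Forskolin+BMP4 replicate 2 (0.13) ended the S-phase call, and leaving out any array except the DMSO arrays ended the G2/M call (0.076 to 0.2). The count of 19 genes came to 0 without either array of the combined treatment, 1 without either BMP4 array, and 3 or 4 without any other array, and to 217 with a trended and robust spread. Among the 12 named genes that passed, 0 passed in all 8 omissions and 8 passed in none, namely Slc35f3, Aqp1, Ct55, Dok4, Pdgfa, Exoc3l2, Depp1 and Lyve1.

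The difference between the forskolin effect with and without BMP4, which is the same as the difference between the BMP4 effect with and without forskolin, asked whether the treatments acted on each other. By limma 0 genes passed, with 900 at an unadjusted p under 0.05 and a smallest adjusted p of 0.88, and 0 passed with a trended and robust spread. The smallest p belonged to Opcml (-1.48 ± 0.17), Atat1 (-1.33 ± 0.17), Itih3 (1.84 ± 0.24), Urgcp (-1.77 ± 0.24) and Itsn2 (1.48 ± 0.22), none past the test. The group means of Opcml, from 3.49 to 4.71, lay below the first quartile of every array, the lowest of which was 5.22. Among BMP targets the difference was -0.07 ± 0.22 for Id1, -0.52 ± 0.20 for Id2, -0.12 ± 0.27 for Smad6 and -0.11 ± 0.28 for Smad7, and none passed. Runx1 differed by 0.05 ± 0.45, with a 95% interval from -1.03 to 1.14. The BMP/SMAD list had a median difference of -0.08 (adjusted p = 0.95) and the cAMP/CREB-responsive list one of 0.05 (adjusted p = 0.8). All 15 interferon-response genes had a positive difference, with a median of 0.71, adjusted p = 9.7e-05 and adjusted p = 0.53 with an estimated correlation; 0 passed over all genes and 3 were higher when adjusted over the list alone. The DMSO arrays held the highest interferon list means, 7.95 and 8.22, against at most 7.40 in the other 6 arrays. Of 22 macrophage and myeloid markers 21 had a positive difference, with a median of 0.12, adjusted p = 0.017 and adjusted p = 0.53 with an estimated correlation. The macrophage call ended without BMP4 replicate 1 (0.23), Forskolin+BMP4 replicate 1 (0.17), DMSO replicate 2 (0.28) or Forskolin replicate 2 (0.066). On simulated data with 2 arrays per group, 7.8% of differences of 1 between the effects and 78% of differences of 2 were recovered. Genes called in one setting and not in the other are not shown to differ.

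**Figure D2:**
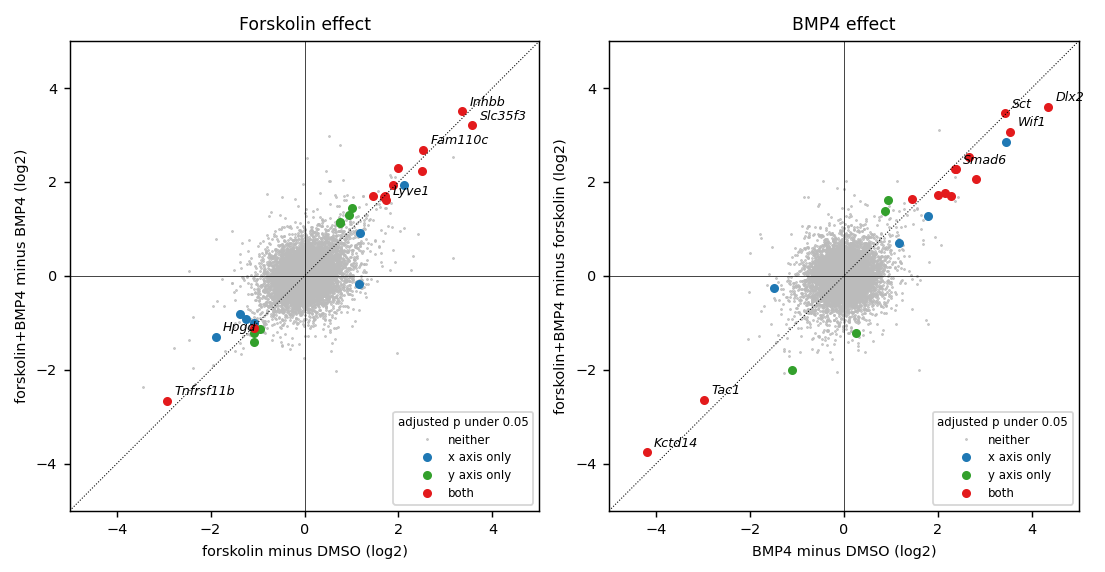
Each point is a gene, with the log2 effect of forskolin without BMP4 against that with BMP4 (left) and the log2 effect of BMP4 without forskolin against that with forskolin (right), coloured by the comparisons in which it passed. Of the 19 genes called on each forskolin axis 12 were called on both, and of the 17 on each BMP4 axis 13 were.

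Each treatment had a pair of effect estimates from separate arrays, while the calls also rest on a spread pooled over all 8 arrays. Of the 19 genes called for forskolin without BMP4 and the 19 called with it, 12 were shared, all in the same direction. For BMP4, 13 genes were shared of 17 called without forskolin and 17 called with it, all in the same direction. With only the arrays compared in the fit, 0 genes were called for forskolin by limma in either setting, and 9 for BMP4 without forskolin and 0 with it, so no call was then shared. The direction does not depend on the pooled spread, and 18 of the 19 forskolin calls and 17 of the 17 BMP4 calls made in the absence of the other treatment had the same direction in its presence. The median size of the forskolin calls was 1.73 without BMP4 and 1.70 for the same genes with it. For the BMP4 calls it was 2.39 without forskolin and 2.27 with it. Across all genes the estimates had a Pearson r of 0.336 for forskolin and 0.181 for BMP4, and genes are not independent replicates. Without Forskolin+BMP4 replicate 1 the forskolin r was 0.217 and the BMP4 r was 0.0983, and without Forskolin replicate 2 the BMP4 r was 0.11.

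Forskolin averaged over both BMP4 settings, with 4 arrays on each side, gave the most calls, 147 genes up and 84 down. Among the 39 cAMP/CREB-responsive genes 8 rose, 0 fell and 31 did not pass, while 22 were higher and 2 lower when adjusted over the list alone. Dusp5 rose by 1.09 ± 0.09 (adjusted p = 0.00749), Pde10a by 1.97 ± 0.17, Pde4d by 1.11 ± 0.11 and Ppargc1a by 1.70 ± 0.19. Pde4b rose by 1.17 ± 0.14 (adjusted p = 0.0181), while Crem (0.69 ± 0.12, adjusted p = 0.0624), Nr4a1 (0.33), Fos (0.27) and Per1 (0.07) did not pass. The list had a median of 0.34, with 32 of 39 members higher (adjusted p = 3.3e-13), and the call held with an estimated correlation (adjusted p = 0.031). The 29 cAMP/PKA pathway components, which carry the signal, passed by camera in none of the 8 contrasts (lowest adjusted p = 0.58).

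In the BMP pathway, the ligand gene Bmp2 rose with forskolin by 0.62 ± 0.09 (adjusted p = 0.0374) and the endothelial BMP target Tmem100 by 1.97 ± 0.18 (adjusted p = 0.00971). Tmem100 was the 1 BMP/SMAD target of 24 that passed, while 2 were higher and 1 lower when adjusted over the list alone, and the list did not pass by camera (median 0.13, adjusted p = 0.054). Id1 (0.07, adjusted p = 0.885), Id2 (0.22), Id3 (0.13), Smad6 (0.08, adjusted p = 0.892), Smad7 (0.13), Bambi (-0.34) and Bmp4 (0.11) did not pass. Bmp2 was the 1 of 25 BMP pathway components to pass, and camera called that list in none of the 8 contrasts (lowest adjusted p = 0.2). By fry, which compares a list with no other genes, the BMP/SMAD targets and the BMP components each had an adjusted p of 0.02 for forskolin averaged over BMP4. The SMAD co-repressor gene Skil rose by 0.65 ± 0.10, the 1 TGF-beta/SMAD3 target of 17 to pass (list median 0.13, adjusted p = 0.054).

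Among blood-forming genes, the stem cell factor receptor gene Kit rose with forskolin by 0.73 ± 0.08 (adjusted p = 0.0129), and Procr, which encodes the endothelial protein C receptor, by 0.59 ± 0.10 (adjusted p = 0.0499). These were the 2 of 19 stem and progenitor surface genes to rise, with 0 falling, a list median of -0.13 and no call by camera in any contrast (lowest adjusted p = 0.69). Mllt3, a regulator of stem cell maintenance, rose by 1.32 ± 0.16 and the transcriptional repressor gene Gfi1 by 0.88 ± 0.14. They were the 2 of 26 haematopoietic transcription factors to rise, with 0 falling (lowest list adjusted p = 0.06). Runx1 differed by -0.01 ± 0.23 (adjusted p = 0.995), Gata2 by 0.23 (adjusted p = 0.453) and Ptprc by 0.33, and none passed. The erythroid list of 14 genes was called nowhere by camera (lowest adjusted p = 0.72).

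With forskolin averaged over BMP4 the flow-induced transcription factor genes Klf2 and Klf4 rose by 0.69 ± 0.08 and 0.83 ± 0.11 (adjusted p = 0.0145 and 0.0234), and the water channel gene Aqp1 rose as well (SE 0.15, adjusted p = 0.00534; 2.00 without and 2.30 with BMP4). These were the 3 of 18 shear-stress-responsive genes to pass, and the list was not called by camera (lowest adjusted p = 0.21), while fry called it here (adjusted p = 0.036). Lyve1 rose by 1.67 ± 0.08, the 1 of 23 endothelial markers to pass, with a list median of 0.08, adjusted p = 0.012 and adjusted p = 0.56 with an estimated correlation. Cdh5, the gene of the sorted surface protein, differed by 0.17 and did not pass. The arterial gap junction gene Gja4 fell by 0.94 ± 0.10, the 1 of 20 arterial and Notch genes to pass (lowest list adjusted p = 0.16), and the list of 8 venous genes was called by camera in no contrast (lowest adjusted p = 0.18). Of 18 angiogenic and permeability genes, Angpt2 (1.06 ± 0.13), S1pr1 (0.55 ± 0.08) and Pgf (0.59 ± 0.09) rose and Nid2 (-0.52 ± 0.08) fell. When adjusted over the list alone 8 were higher and 3 lower, with a list median of 0.28, adjusted p = 0.012 and adjusted p = 0.43 with an estimated correlation. Leaving out DMSO replicate 1 (0.057 for both) or Forskolin+BMP4 replicate 1 (0.12 endothelial, 0.082 angiogenic) ended these 2 list calls.

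Of 13 prostaglandin pathway genes 2 fell with forskolin averaged over BMP4, Hpgd by 1.59 ± 0.11 (adjusted p = 0.00534) and the prostaglandin and cAMP exporter gene Abcc4 by 0.67 ± 0.09 (adjusted p = 0.0255). The other 11 did not pass, 8 of the 13 were higher in value, and when adjusted over the list alone 2 were higher and 3 lower. Camera did not call that list (median 0.05, adjusted p = 0.47; lowest of the 8 contrasts 0.25), and fry called it in both treatments against BMP4 (adjusted p = 0.038) and not here. Of the 19 S-phase genes 17 were lower and 0 passed over all genes, while 4 were lower when adjusted over the list alone, Cdc6 (-0.39), Ccne2 (-0.49), Ccne1 (-0.39) and Rrm2 (-0.34). This list had a median of -0.17, with adjusted p = 0.0019 and adjusted p = 0.39 with an estimated correlation. Of 19 G2/M genes 15 were lower, with a median of -0.10, adjusted p = 0.025 and adjusted p = 0.36 with an estimated correlation. The G2/M call ended without any array except DMSO replicate 2 and BMP4 replicate 2 (0.062 to 0.088).

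Single members of other lists passed with forskolin averaged over BMP4, in lists that camera did not call for forskolin. Cd14 rose by 2.02 ± 0.16, 1 of 22 macrophage and myeloid markers, and the smooth muscle gene Tagln fell by 0.76 ± 0.09, 1 of 19 mesenchymal markers. The endothelin receptor gene Ednrb rose by 1.18 ± 0.10, 1 of 11 neural crest and sympathetic markers (lowest list adjusted p = 0.093). Bcl6 rose by 0.63 ± 0.10, 1 of 13 JAK/STAT cytokine-response genes (0.38), Ddit4 by 0.51 ± 0.08, 1 of 17 unfolded protein and ATF4 response genes (0.054), and Ndrg1 by 0.92 ± 0.11, 1 of 15 hypoxia and glycolysis genes (0.31). Of 14 MAPK feedback genes Ier3 rose by 0.73 ± 0.11, and Spry4 and Spred1 fell by 0.79 ± 0.11 and 0.63 ± 0.10 (0.12). Camera made no call in any contrast for the 21 NF-kappaB and inflammatory genes (0.24), the 16 p53 target genes (0.4), the 9 heat-shock genes (0.084) or the 14 cholesterol synthesis genes (0.41). For forskolin averaged over BMP4 fry, which asks if a list's genes move one way and compares them with no others, called the JAK/STAT (fry adjusted p = 0.02), unfolded protein and ATF4 (0.0043), hypoxia (0.02), heat-shock (0.036) and cholesterol (0.025) lists, whose medians lay between -0.04 and 0.14.

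Ifit2 fell by 0.85 ± 0.14 with forskolin averaged over BMP4, the 1 of 15 interferon-response genes to pass, while 4 were lower when adjusted over the list alone. The interferon list had a median of -0.32, with adjusted p = 1e-04 and adjusted p = 0.36 with an estimated correlation. With BMP4 present its median was -0.09, and the values of Ifit2 in the BMP4 arrays overlapped those in the forskolin arrays. Of all 231 called genes, 224 had the 4 forskolin arrays wholly above or below the other 4 arrays. Hepatic transcripts had a median of -0.66 over 20 genes, with 18 lower and none past the test (camera p = 8.7e-06, and 0.17 with an estimated correlation). Leaving out any 1 of the 8 arrays brought the count of 231 to between 26 and 95, and of the 33 named genes that passed, 4 (Lyve1, Aqp1, Hpgd and Cd14) passed in all 8 omissions. In none of the omissions did 17 of the 33 pass, namely Bmp2, Skil, Gfi1, Kit, Procr, Klf2, Abcc4, Tagln, Bcl6, Ifit2, Ddit4, Spry4, Ier3, Spred1, S1pr1, Nid2 and Pgf. A trended and robust spread gave 616 genes, and 96 of the 231 genes also differed by at least 1 on the log2 scale.

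**Figure D3:**
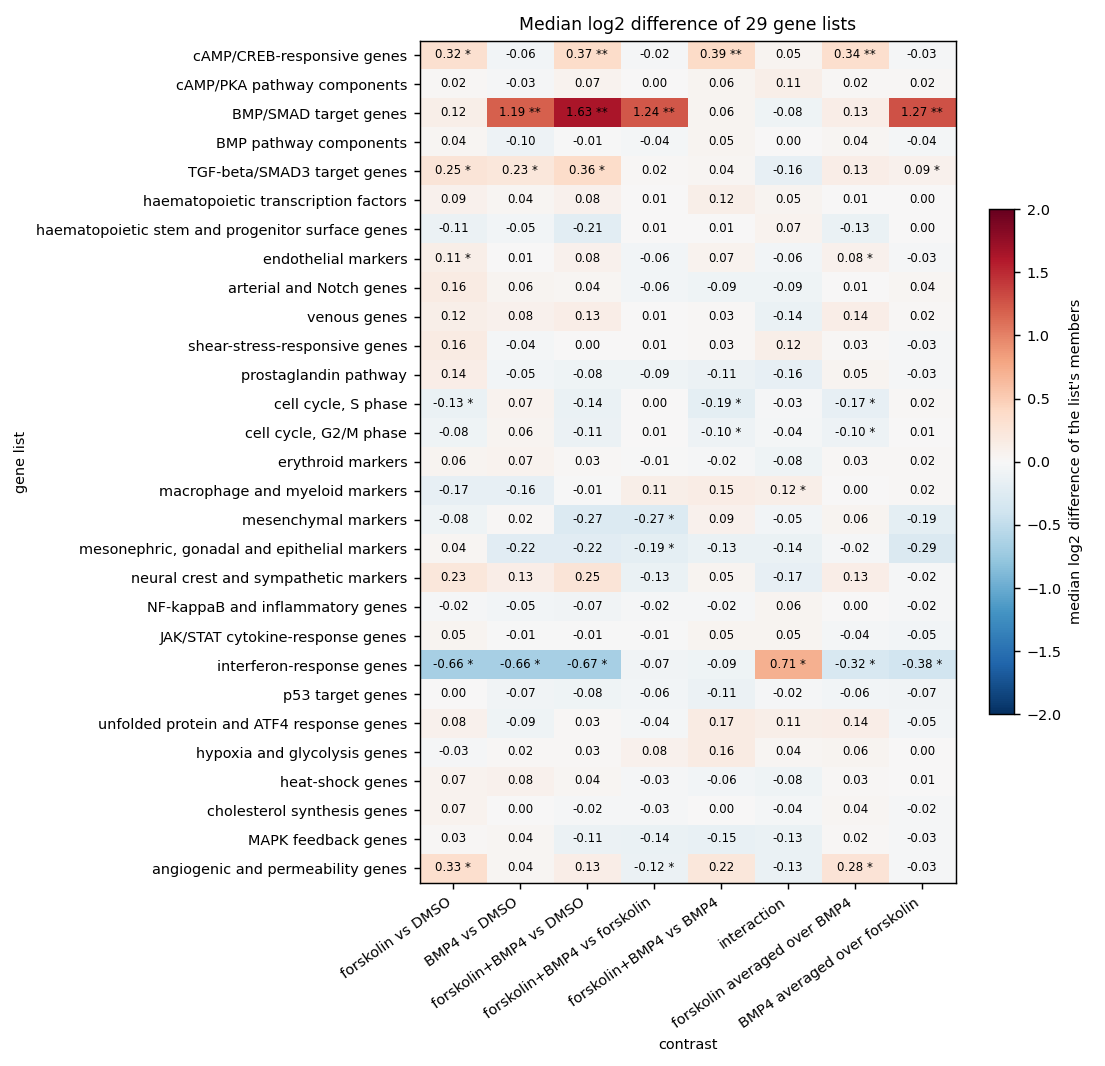
Median log2 difference of each of the 29 gene lists (vertical) in the 8 contrasts (horizontal), with 1 star where camera passed and a pair of stars where it also passed with an estimated correlation. The BMP/SMAD list had a median of 1.27 for BMP4 averaged over forskolin and the cAMP/CREB list one of 0.34 for forskolin averaged over BMP4.

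BMP4 averaged over both forskolin settings, again with 4 arrays on each side, raised 31 genes and lowered 10, and in each of the 41 genes the groups of 4 arrays did not overlap. Dlx2 rose by 3.98 ± 0.16 (15.7-fold, adjusted p = 0.000788), Nog by 2.60 ± 0.11 (adjusted p = 0.000915), Smad6 by 2.33 ± 0.13 and Id2 by 1.53 ± 0.10. Id1 rose by 1.07 ± 0.11 and Id3 by 0.66 ± 0.08 (adjusted p = 0.0257 and 0.042), and Smad7 rose by 1.50 ± 0.14 (adjusted p = 0.0169). Of the 24 BMP/SMAD target genes 13 rose, 0 fell and 11 did not pass, while 21 were higher when adjusted over the list alone. The list median was 1.27, with adjusted p = 1.9e-49, and the call held with an estimated correlation (adjusted p = 0.0022). The sphingosine receptor gene S1pr3 fell by 0.97 ± 0.09, the 1 angiogenic gene to pass. Bambi (0.27), Gata2 (0.46), Runx1 (0.23), Bmp4 (-0.31) and Kit (-0.10) did not pass. The TGF-beta/SMAD3 list had a median of 0.09, with 3 of 17 higher when adjusted over the list alone (adjusted p = 0.037, and adjusted p = 0.78 with an estimated correlation). That call ended without Forskolin+BMP4 replicate 1 (0.064), DMSO replicate 2 (0.11), Forskolin replicate 2 (0.57), BMP4 replicate 2 (0.072) or Forskolin+BMP4 replicate 2 (0.14). The interferon list had a median of -0.38, with 0 past the test over all genes, 5 lower when adjusted over the list alone, adjusted p = 7.5e-09 and adjusted p = 0.15 with an estimated correlation. With forskolin present its median was -0.07 and it was not called, and the DMSO arrays held its highest means, 7.95 and 8.22 against at most 7.40. Leaving out any 1 of the 8 arrays brought the count of 41 to between 16 and 29, and of the 8 named genes that passed, Dlx2, Nog, Smad6 and Id2 passed in all 8 omissions while Id1 and Id3 passed in none.

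Of the 231 genes called for forskolin and the 41 called for BMP4, 3 were shared, and these 3 were named after their values were seen. Tac1 rose with forskolin by 1.97 and fell with BMP4 by 2.81, and Kctd14 rose by 1.47 and fell by 3.98. Olfm2, an olfactomedin-family gene, rose by 0.53 with forskolin and by 0.93 with BMP4. Of the 232 list tests 31 were called by camera, 7 of them also with an estimated correlation, and all 7 belonged to the cAMP/CREB-responsive and BMP/SMAD target lists. The median, mean and test of a list differed in sign in 34 of the 232 tests, of which 0 were called by camera.

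**Figure D4:**
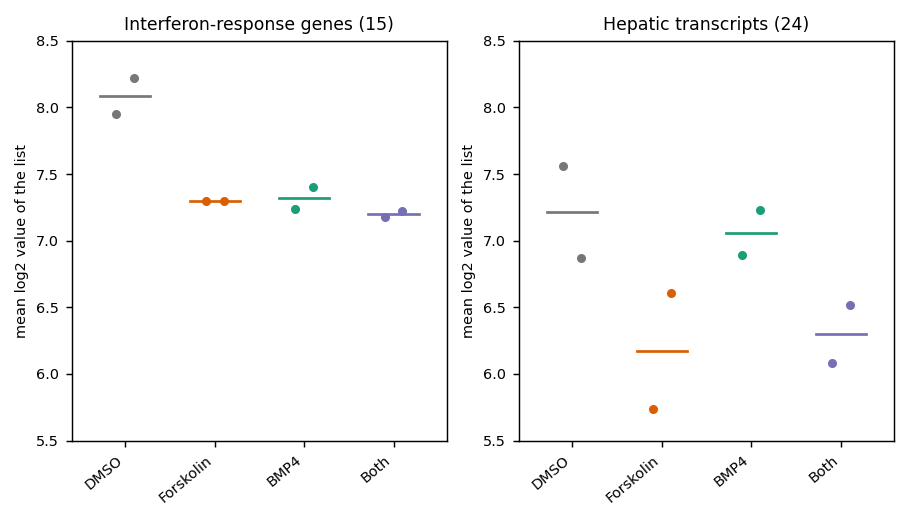
Mean log2 expression (vertical axis) of the 15 interferon-response genes and of 24 hepatic transcripts in each of the 8 arrays. The interferon mean was 7.95 and 8.22 in the DMSO arrays and at most 7.40 in the others.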

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

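The tests of the interferon-response pattern were chosen only after the result was seen, while those of hepatic and peptide genes used lists written after some members had been noticed and counted members not seen before.

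The effect of forskolin differed with and without BMP4 by the test of the difference itself in 2 lists, under the preset correlation only. The interferon-response genes had a camera adjusted p of 9.7e-05 (median difference 0.71, 15 of 15 members higher) and the macrophage and myeloid markers one of 0.017 (median difference 0.12, 21 of 22 higher). With an estimated correlation both had an adjusted p of 0.53, which is not past the threshold.

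In the interferon list the DMSO arrays stood apart, with all 15 members above the mean of the other 6 arrays, by a median of 0.66. Array scaling is argued against, since no more than 1e-04 of 10000 matched random lists had as large a median excess, the smallest share this test reports. The macrophage list as a whole did not share the excess, with a median of 0.06 (SD of members 0.45). Its members were mixed. C1qc and Mrc1 were higher in both DMSO arrays than in any other array, while Csf1r and Cd68 were not. The list therefore cannot decide on more macrophage RNA in the DMSO arrays. 1 outlying DMSO array is argued against because 2 DMSO arrays had list means above all 6 other arrays (7.95 and 8.22 against at most 7.40). Forskolin and BMP4 may each lower these genes, with medians of -0.66 and -0.66, but this cannot be told apart from a source specific to the DMSO cultures, since both comparisons use the same DMSO arrays.

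Hepatic transcripts differed between arrays and were lower with forskolin, with list means of 7.56 and 6.87 in DMSO, 6.89 and 7.23 in BMP4, 5.74 and 6.61 in forskolin, and 6.08 and 6.52 in the combined treatment. RNA from hepatic cells in some sorted samples may be the source. The 20 genes not seen before had a mean pairwise correlation of 0.39 over the 8 arrays. It was matched or passed by no more than 1e-04 of 10000 matched random lists, the smallest share this test reports. Group means were not removed, so a fall of these genes with forskolin would also raise this correlation. It cannot tell such a fall from hepatic RNA. A sort for VE-cadherin should remove most such cells. Lowering by forskolin also stays open, with a median of -0.66 (camera p = 8.7e-06, and 0.17 with an estimated correlation), and no single gene passed, the smallest adjusted p being those of Ttr (-2.90, adjusted p = 0.0905) and Fgg (-2.17, adjusted p = 0.0978). Among abundant members, Afp ranged from 6.81 in Forskolin replicate 1 to 11.21 in DMSO replicate 1, and Alb from 5.76 to 9.05 in the same arrays.

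Neuropeptide and peptide-hormone genes appeared among the forskolin rises, 6 of them past the test with a median of 1.65, Npy, Tac1, Nmb, Vgf, Nts and Cartpt. Over all 47 measured members the median was 0.09. The 38 members not seen before had a median of -0.041 (SD 0.49), with 17 higher and 21 lower (camera p = 0.054, and 0.087 with an estimated correlation). Camera does not test the median, so the sign of that median does not give the direction of the test. All 6 that passed were among the members left out, so these 38 cannot decide on a rise of the whole class. Of the 47 members, those closest to passing by limma all rose. They included Pnoc (0.92, adjusted p = 0.0589), Nppc (0.96, 0.0629), Cck (0.66, 0.0646) and Scg2 (1.25, 0.0684). Among falls the smallest adjusted p was 0.295, for Nppb (-0.51). In both treatments against BMP4 the same 38 had a median of 0.08 with 21 higher (camera p = 0.034, and 0.068 with an estimated correlation), and in forskolin against DMSO a median of 0.03 with 21 higher (camera p = 0.16). With forskolin averaged over BMP4 the neural crest and sympathetic list had a median of 0.13 (SD 0.41), with 7 members higher and 4 lower. The 6 peptide genes, with their median of 1.65, were picked for passing and this list was not. Setting one against the other therefore cannot decide on RNA from neural crest or sympathetic cells. A direct effect of cAMP on the 6 genes that passed was not tested and stays open. The peptide list overlaps the cAMP/CREB-responsive list, which also holds Vgf, Vip, Penk and Sst.

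Probe sets without a single gene symbol, which the comparisons of genes do not use, also changed. With all probe sets tested together, 5 such probe sets changed in both treatments against DMSO, 2 in both treatments against BMP4, 16 with forskolin averaged over BMP4 and 2 with BMP4 averaged over forskolin. With forskolin averaged over BMP4, 7 rose and 9 fell, the largest by 2.94 and by -1.22. With 2 arrays per group, a comparison within a group cannot tell which of its arrays is outlying.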

How the results depend on the processing

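The tests of all probe sets, named or not, were chosen after the data had been seen, and the other alternatives were chosen before. The alternatives were quantile normalization repeated on the deposited values, subtraction of array medians, array weights, the mean of a gene's probe sets, removal of the lowest 30% of genes by mean, a trended and robust spread, a replicate block, a fit of only the arrays compared, a minimum log2 difference of 1, omission of each array in turn, and for lists fry and an estimated correlation. Each changed 1 choice, except that trend and robust were set together and that an estimated correlation also changes the degrees of freedom. The pseudocount alternative was not run because the values were already log2. The replicate block was not rerun for the correlations across genes because it leaves group means unchanged. When 1 array was left out, the lone array of its group was assumed to vary like the other groups.

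Of the 114 named results that passed, 1771 alternative values were obtained, of which 1008 kept direction and call, 763 kept direction but lost the call, and 0 reversed. The count of 0 reversals is no evidence of robustness. In the pairwise comparisons all called genes had groups of arrays that did not overlap, so leaving out an array could not reverse them. The same held for 224 of the 231 genes called for forskolin averaged over BMP4 and all 41 for BMP4 averaged over forskolin. A trended and robust spread, a replicate block and a fit of only the arrays compared leave the differences between group means unchanged. Calls were also gained. Of the named results that had not passed, 25 passed with a trended and robust spread and 7 without the lowest 30% of genes. Repeated quantile normalization and subtraction of array medians each added 2. The largest shift of the median of all genes by a scaling choice was 0.021 on the log2 scale, from subtraction of array medians in both treatments against forskolin. Signal over background was unknown, since no background or detection values accompany the table, so how far it limits dim genes could not be measured.

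The reported counts of changed genes were 19 for forskolin against DMSO, 17 for BMP4 against DMSO, 85 for both treatments against DMSO, 17 for both treatments against forskolin, 19 for both treatments against BMP4, 231 for forskolin averaged over BMP4 and 41 for BMP4 averaged over forskolin. A trended and robust spread, with both options set together and not apart, gave 262 for forskolin against DMSO, 31 for BMP4 against DMSO, 374 for both treatments against DMSO, 39 for both treatments against forskolin, 217 for both treatments against BMP4, 616 for forskolin averaged over BMP4 and 80 for BMP4 averaged over forskolin. Removal of the lowest 30% of genes gave 86 for forskolin against DMSO, 134 for both treatments against DMSO and 44 for both treatments against BMP4. It gave 18 for BMP4 against DMSO and 14 for both treatments against forskolin. This removal leaves fewer tests and also refits the spread, and the cause of the changes was not tested. A fit of only the arrays compared, which leaves fewer residual degrees of freedom, gave 0 for forskolin against DMSO, 9 for BMP4 against DMSO, 14 for both treatments against DMSO, 0 for both treatments against forskolin and 0 for both treatments against BMP4. Repeated quantile normalization gave 47 for forskolin against DMSO, and the cause was not tested. Requiring a log2 difference of at least 1 gave 96 for forskolin averaged over BMP4, and a test of all probe sets gave 10 for forskolin against DMSO and 12 for both treatments against BMP4.

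With any 1 of the 8 arrays left out, the counts ranged from 0 to 7 for forskolin against DMSO, from 0 to 14 for BMP4 against DMSO, from 8 to 35 for both treatments against DMSO, from 0 to 3 for both treatments against forskolin, from 0 to 4 for both treatments against BMP4, from 26 to 95 for forskolin averaged over BMP4 and from 16 to 29 for BMP4 averaged over forskolin. The interaction stayed at 0 genes by limma under each of these omissions.

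With a replicate block, which uses a residual degree of freedom, the counts were 6 for forskolin against DMSO, 31 for both treatments against DMSO, 8 for both against forskolin, 5 for both against BMP4, 123 for forskolin averaged over BMP4 and 19 for BMP4 averaged over forskolin. The replicate block ended 49 of the 114 calls of named genes. With BMP4 averaged over forskolin these included Id1 (adjusted p = 0.0839) and Id3 (0.112). With forskolin averaged over BMP4 they included Bmp2 (0.0769), Mllt3 (0.0524), Gfi1 (0.0767), Klf4 (0.053) and Procr (0.0664). The replicate block also ended 4 list calls. The adjusted p was 0.072 for the TGF-beta/SMAD3 list with BMP4 averaged over forskolin and 0.089 for the G2/M list in both treatments against BMP4. It was 0.065 for the mesenchymal and 0.074 for the angiogenic list in both treatments against forskolin. Deviations of arrays with the same replicate number had correlations from -0.04 to 0.2 between groups.

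With an estimated correlation 7 of 31 list calls held. By construction that setting also judges a list against the 4 residual degrees of freedom instead of the number of genes. The cAMP/CREB list had an estimated correlation of 0.00, no higher than the preset 0.01, so its lost call came from the degrees of freedom. In forskolin against DMSO the adjusted p became 0.068 for the cAMP/CREB list, 0.22 for the interferon list and 0.48 for each of the TGF-beta/SMAD3, endothelial, S-phase and angiogenic lists. In BMP4 against DMSO it became 0.8 for the TGF-beta/SMAD3 list and 0.1 for the interferon list, and in both treatments against DMSO 0.68 and 0.075. Against forskolin, the combined treatment gave 0.77 for the mesenchymal and angiogenic lists and 0.74 for the mesonephric list. Against BMP4, it gave 0.57 for the S-phase list and 0.46 for the G2/M list. For the difference between effects it became 0.53 for the macrophage and interferon lists. With forskolin averaged over BMP4 it became 0.56 for the endothelial, 0.39 for the S-phase, 0.36 for the G2/M and interferon, and 0.43 for the angiogenic list. With BMP4 averaged over forskolin it became 0.78 for the TGF-beta/SMAD3 list and 0.15 for the interferon list.

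The directional fry test, which compares a list with no other genes, made 35 calls in the 232 list tests against 31 by camera, with 18 by both. It made 17 calls that camera did not, 8 of them for forskolin averaged over BMP4, where it called 14 lists against 6. Of the calls lost with an estimated correlation it also ended 13, and no others. In forskolin against DMSO its adjusted p was 0.15 for the TGF-beta/SMAD3 list, 0.052 for the endothelial and angiogenic lists and 0.077 for the S-phase list. For the TGF-beta/SMAD3 list it was 0.56 with BMP4 against DMSO, 0.13 with both treatments against DMSO and 0.35 with BMP4 averaged over forskolin. The combined treatment against forskolin gave 0.47 for the mesenchymal list and 0.41 for the mesonephric and angiogenic lists, and against BMP4 it gave 0.087 for the S-phase list. For the difference between effects it was 0.39 for the macrophage list and 0.23 for the interferon list.

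Repeated quantile normalization brought the adjusted p to 0.056 for the endothelial list in forskolin against DMSO and to 0.057 for the G2/M list in both treatments against BMP4. The mesenchymal and angiogenic lists came to 0.081 in both treatments against forskolin. Without the lowest 30% of genes the adjusted p was 0.056 for the macrophage list in the difference between effects. It was 0.55 for the mesenchymal, 0.067 for the mesonephric and 0.09 for the angiogenic list in both treatments against forskolin. For these list changes the cause was not tested.

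Some list calls ended when 1 array was left out. In forskolin against DMSO the adjusted p ranged from 0.00061 to 0.34 for the TGF-beta/SMAD3 list (ended without Forskolin replicate 1), from 0.02 to 0.07 for the endothelial list (DMSO replicate 1 or either forskolin array), from 0.013 to 0.32 for the S-phase list (DMSO or Forskolin replicate 2) and from 0.01 to 0.052 for the angiogenic list (Forskolin replicate 2). In both treatments against forskolin it ranged from 0.023 to 0.47 for the mesenchymal list (either DMSO array, either array of both treatments or Forskolin replicate 1). In the same comparison it ranged from 0.018 to 0.19 for the mesonephric list (either array of both treatments or Forskolin replicate 2) and from 0.035 to 0.57 for the angiogenic list (all but Forskolin+BMP4 replicate 1). In both treatments against BMP4 it ranged from 0.011 to 0.13 for the S-phase list (BMP4 replicate 1 or Forskolin+BMP4 replicate 2) and from 0.05 to 0.2 for the G2/M list (all but the DMSO arrays). For the difference between effects it ranged from 0.00019 to 0.28 for the macrophage list (BMP4 or Forskolin+BMP4 replicate 1, DMSO or Forskolin replicate 2). With forskolin averaged over BMP4 it ranged from 0.008 to 0.12 for the endothelial list and from 0.0093 to 0.082 for the angiogenic list (each DMSO or Forskolin+BMP4 replicate 1), and from 0.027 to 0.088 for the G2/M list (all but DMSO and BMP4 replicate 2). With BMP4 averaged over forskolin it ranged from 0.00046 to 0.57 for the TGF-beta/SMAD3 list (Forskolin+BMP4 replicate 1 or any array of replicate 2). Fewer arrays leave fewer residual degrees of freedom, and beyond that the cause was not tested.

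The correlation across genes of the forskolin effects with and without BMP4 was 0.429 and that of the BMP4 effects 0.233 without the lowest 30% of genes, against 0.336 and 0.181 as reported. Leaving out 1 array moved them to between 0.217 and 0.358, and 0.0983 and 0.208.

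The sign of genes near 0 that did not pass the test reversed in 68 values, all under the omission of 1 array, and the cause was not tested. In forskolin against DMSO the log2 values ranged for Id1 from -0.03 to 0.24, Smad6 from -0.13 to 0.4, Smad7 from -0.11 to 0.47 and Runx1 from -0.43 to 0.37. In BMP4 against DMSO the log2 values ranged for Pde4b from -0.32 to 0.07, Pde4d from -0.08 to 0.21 and Bmp4 from -0.29 to 0.09. In both treatments against DMSO the log2 values ranged for Per1 from -0.15 to 0.29, Runx1 from -0.13 to 0.57 and Ptprc from -0.06 to 0.02. In both treatments against forskolin the log2 values ranged for Nr4a1 from -0.13 to 0.14, Fos from -0.13 to 0.14, Crem from -0.01 to 0.22, Pde4b from -0.34 to 0.05, Pde4d from -0.05 to 0.2 and Runx1 from -0.15 to 0.65. In both treatments against BMP4 the log2 values ranged for Per1 from -0.39 to 0.05, Id1 from -0.12 to 0.19, Id2 from -0.12 to 0.05, Smad6 from -0.07 to 0.11, Bmp4 from -0.21 to 0.01 and Runx1 from -0.33 to 0.37. In the difference of the forskolin effect with and without BMP4 the log2 values ranged for Nr4a1 from -0.06 to 0.21, Pde4b from -0.21 to 0.18, Pde4d from -0.14 to 0.16, Id1 from -0.23 to 0.09, Smad6 from -0.38 to 0.15, Smad7 from -0.39 to 0.18, Runx1 from -0.35 to 0.45 and Gata2 from -0.19 to 0.02. In forskolin averaged over BMP4 the log2 values ranged for Per1 from -0.05 to 0.18, Id1 from -0.01 to 0.15, Smad6 from -0.05 to 0.21, Smad7 from -0.02 to 0.27 and Runx1 from -0.21 to 0.19. In BMP4 averaged over forskolin the log2 values ranged for Nr4a1 from -0.1 to 0.04, Crem from -0.2 to 0.01, Pde4d from 0 to 0.14, Per1 from -0.11 to 0.12 and Cdh5 from -0.07 to 0.00.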

Other observations

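No test in this part was chosen only after its result was seen, although the gastric list was written after 3 of its members had been noticed.

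Among genes not yet described, chosen after their values were seen, forskolin averaged over BMP4 raised 2 more phosphodiesterase genes, Pde7b by 1.42 ± 0.15 and Pde3a by 1.21 ± 0.17, whose products break down cyclic nucleotides. It also raised Cyp11a1, the enzyme gene of the first step of steroid synthesis, by 1.65 ± 0.19, and Prokr1, a receptor gene for prokineticins, by 1.32 ± 0.15. The adhesion gene Madcam1 fell by 1.30 ± 0.14, the chemerin receptor gene Cmklr1 fell by 1.12 ± 0.18 and the platelet chemokine gene Ppbp fell by 1.16 ± 0.15.

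The genes named next for BMP4 averaged over forskolin were also chosen after their values were seen. The cardiac and endodermal factor gene Gata5 rose by 2.05 ± 0.23, the mesenchymal homeobox gene Prrx2 by 1.55 ± 0.09, the BMP-family gene Gdf10 by 1.86 ± 0.12 and the BMP antagonist gene Chrdl2 by 1.47 ± 0.18. The WNT agonist gene Rspo1 fell by 1.07 ± 0.12, and Wif1 and Dkk1, both WNT antagonists, rose by 3.31 ± 0.16 and 3.15 ± 0.22. The hormone precursor gene Pomc fell by 1.70 ± 0.18 and the lysophosphatidic acid receptor gene Lpar1 fell by 1.01 ± 0.11.

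The gastric genes Gkn1, Gkn2 and Pga5 had their highest values in Forskolin+BMP4 replicate 2, at 9.41, 8.15 and 7.43. Gkn1 and Gkn2 stood at 6.83 and 6.47 in Forskolin+BMP4 replicate 1 and at 6.87 and 6.04 in Forskolin replicate 2. Of 12 gastric genes not seen before, 3 had their highest value in Forskolin+BMP4 replicate 2 (one-sided exact binomial p = 0.18), and their mean there was 6.01, against 6.01 in DMSO replicate 2 and 6.10 in Forskolin replicate 2. These values leave RNA from gastric cells in 1 sorted sample undecided, and a sort for VE-cadherin should remove most such cells.

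The 8 arrays can be split into 4 and 4 in 35 ways. The split by forskolin gave 307 genes in a fit of 2 groups and was the 1 split of 35 with as many, against a highest other count of 42. A share of 1 in 35 is the smallest that this count can give. The split by BMP4 gave 42 genes and 2 of 35 splits gave as many. The other split with as many was the one by forskolin, with 307 genes, several times the BMP4 count, which is the other treatment and a known structure of the samples. With that split above it, 2 of 35 was the lowest share possible, so this count cannot decide on chance for BMP4. The remaining 33 splits each gave 0 genes by limma. Each of these mixes the treatments within a side, so treatment effects widen its spread, and the comparison of splits cannot decide on chance. In the arrays with forskolin, which share none with the others, 17 of the 17 genes called for BMP4 against DMSO had the same direction.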
